A study of Homo sapiens with 26 samples.

How the data were processed

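RNA sequencing was analysed for 26 libraries from biopsies of metastatic lesions of 13 patients with pancreatic carcinoma that had not been treated before. Each patient gave 1 library before and 1 library after 8 weeks of gemcitabine, nab-paclitaxel and indoximod. Per the labels' protocols, RNA was extracted from formalin-fixed, paraffin-embedded tissue with a Norgen kit, and libraries were made with KAPA RNA HyperPrep and ribosomal RNA depletion. The submitters' processing notes name FastQC, Bowtie2, TopHat2 2.1.1, Cufflinks 2.2.1, DESeq2 and R 4.0.3, and the builds hg38 and GRCh38.p12, without saying which step each served. The counting tool, its strand setting and the gene annotation are not given in the sources used here. Reads shared between near-identical genes, or between a gene and an overlapping or antisense partner, could therefore have been assigned in ways that cannot be checked.

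The deposited values were whole-number counts per gene symbol, not normalized, in 1 file per library with 27973 rows. The last 2 rows of each file named no gene. They held the reads outside any feature, which made up 48.7% to 75.0% of all counted reads, and the ambiguous reads, and both were left out of library sizes and tests. The 117 sex-linked genes that must not be reported for people were removed before every step, which left 27854 gene rows. Gene counts ranged from 3841300 to 15082681 per library. Counts are of reads without molecular identifiers, so the precision they give covers counting error only.

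Libraries were assigned to the time points and to patients from the sample labels, which name the subject and the time point. The labels also show 2 sets of libraries, and the smaller set held 2 libraries, both post-treatment, so that set and the time point cannot be separated within it. Pre- and post-treatment libraries of the same patient were paired because they came from the same donor. As a check of the pairing, the deviations of log2 CPM (reads of a gene scaled to the library total) from the time point means were correlated. The median correlation was 0.43 for libraries of the same patient, with a range of -0.31 to 0.86, and 10 of 13 pairs were above 0.1. The median was -0.05 for libraries of different patients.

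Genes were filtered with filterByExpr, normalized by TMM and tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test with robust estimation (glmQLFit and glmQLFTest). The model had a term for each patient and a term for the time point. Tests were two-sided and p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The standard error of a log2 fold change was derived from the F statistic. A set of 55 gene lists (cell types, pathways and tissues) was fixed before the data were examined, and 48 had at least 5 members past the filter. The lists of acinar and islet cells, B cells, erythroid cells and platelets, intestine, lung, NK cells and mitochondrially encoded genes had fewer and were not tested. Some list members, among them the immunoglobulin and T-cell receptor constant genes, were not matched to a symbol in the files. A list score was the mean log2 CPM of the members, with a prior count of 2. The 13 differences between post- and pre-treatment scores were tested by an exact two-sided sign-flip permutation test, which has 8192 sign patterns for 13 patients, and adjusted over the 48 lists. Fry and camera of limma 3.58.1 were alternatives. Correlations between list changes over patients were chosen after the data were seen and used 100000 permutations (1e+05).

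The rule for the named genes was also fixed before the data were examined. It took, among genes past the threshold that moved the same way in at least 10 patients and had a mean log2 CPM of at least 0, the 12 largest rises and the 12 largest falls. Where fewer than 5 passed in a direction, the 8 genes with the smallest p in that direction were named as not passing. It also took a set of study genes whatever their result, and up to 4 members with the smallest p of each list described. Some members that this rule takes are not reported here. Gene positions are those of GENCODE on GRCh38.

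The procedure was tested on simulated counts made from the real means and library sizes, with 15810 genes of which 200 were changed. It recovered 63% of the genes changed by 1 on the log2 scale and 93% of those changed by 2. Of the 161 genes called, 3.11% were false, and 0 genes were called when nothing had been changed. Each gene was drawn on its own with the same change in every patient, so tissue shifts shared by many genes were absent. These shares therefore do not show how many real changes of that size were missed. The list test was run on random normal differences, not on simulated counts or gene lists. It gave a p under 0.05 in 3.9% of the sets with no change.

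The alternatives tried were other size factors, DESeq2 1.42.0, limma-voom with quality weights, no and stricter count filters, no patient term, other prior counts, and the median over list members. Others were fits without each patient, fits without the smaller library set, and fits with library size, the hepatocyte score or the carcinoma epithelial score as a covariate. A list of epidermal genes was written after the data were seen, and libraries with KRT1 above 50 CPM were counted as holding it. Files were read with Python 3.11.15 and pandas 2.3.3.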

Results

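Gene expression was measured by RNA sequencing in 26 biopsies of metastatic lesions from 13 patients with pancreatic carcinoma. Each patient was sampled before treatment and after 8 weeks of gemcitabine and nab-paclitaxel, both cytotoxic drugs, with indoximod. Indoximod acts on the tryptophan and kynurenine pathway, in which IDO1, IDO2 and TDO2 carry out the first step. Gene counts ranged from 3841300 to 15082681 in the 13 pre-treatment libraries and from 3982244 to 11991439 in the 13 post-treatment libraries. The labels show 2 sets of libraries, and the smaller set held only 2 libraries, both post-treatment, from 2 patients. No difference in gene counts was detected between the time points (higher in 7 of 13 patients, exact sign-flip permutation p = 0.465). The share of counts taken by the 10 highest genes was 6.50% ± 2.66 (SD, n = 13) before and 8.90% ± 2.37 (SD, n = 13) after treatment, and it was higher in 11 of 13 patients (exact sign-flip permutation p = 0.0276).

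The comparison of post- with pre-treatment biopsies asked which genes changed over the 8 weeks. The genes that rose included DSG1, a desmosomal cadherin of stratified epithelium, LTF, the neutrophil granule protein lactoferrin, and FBLN1, a matrix glycoprotein. TK1, the thymidine kinase of dividing cells, and BRIP1, a helicase of DNA repair, fell. DSG1 rose by a log2 fold change of 4.05 ± 0.70 (SE, 13 pairs) and was higher in 13 of 13 patients (adjusted p = 0.0411, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, as for all genes). LTF rose by 2.68 ± 0.46 (SE) from a mean of 1.28 to 10.4 CPM, and FBLN1 by 1.63 ± 0.28 (SE) from 36.7 to 122.1 CPM. TK1 fell by 1.66 ± 0.26 (SE) on the log2 scale, from 23.6 ± 10.7 (SD, n = 13) to 8.02 ± 5.30 (SD, n = 13) CPM, and was lower in 12 of 13 patients (adjusted p = 0.0392). BRIP1 fell by 0.82 ± 0.13 (SE), from 17.9 to 10.3 CPM, also in 12 of 13 patients.

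The smallest adjusted p belonged to CHL1, a neural cell adhesion molecule, which rose by 2.15 ± 0.25 (SE) on the log2 scale (12 of 13 patients, adjusted p = 0.00429). BOC, a co-receptor of hedgehog signalling, rose by 1.13 ± 0.14 (SE) in 13 of 13 patients (adjusted p = 0.00789). The other genes that rose under the naming rule were CHRDL1, a secreted antagonist of bone morphogenetic proteins, at 2.59 ± 0.37 (SE), SCN7A, a sodium channel, at 2.48 ± 0.42, PLCXD3 at 2.17 ± 0.37, MMRN1, a multimerin of endothelium and platelets, at 1.94 ± 0.32, ANKS1B at 1.82 ± 0.29, UBE2QL1 at 1.81 ± 0.29 and SAMD5 at 1.67 ± 0.27. Their adjusted p-values lay between 0.0205 and 0.0411. SIGLEC1, a macrophage lectin (0.70 ± 0.12, SE), and ASAP3 (0.91 ± 0.16, SE) also passed and are named after their values were seen. On GRCh38, CHL1 lies on chromosome 3 at 196596 to 409417, BOC on chromosome 3 at 113211003 to 113287459, DSG1 on chromosome 18 at 31318089 to 31357029, TK1 on chromosome 17 at 78174075 to 78187233 and BRIP1 on chromosome 17 at 61681266 to 61863521. All are protein-coding genes.

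**Figure D1:**
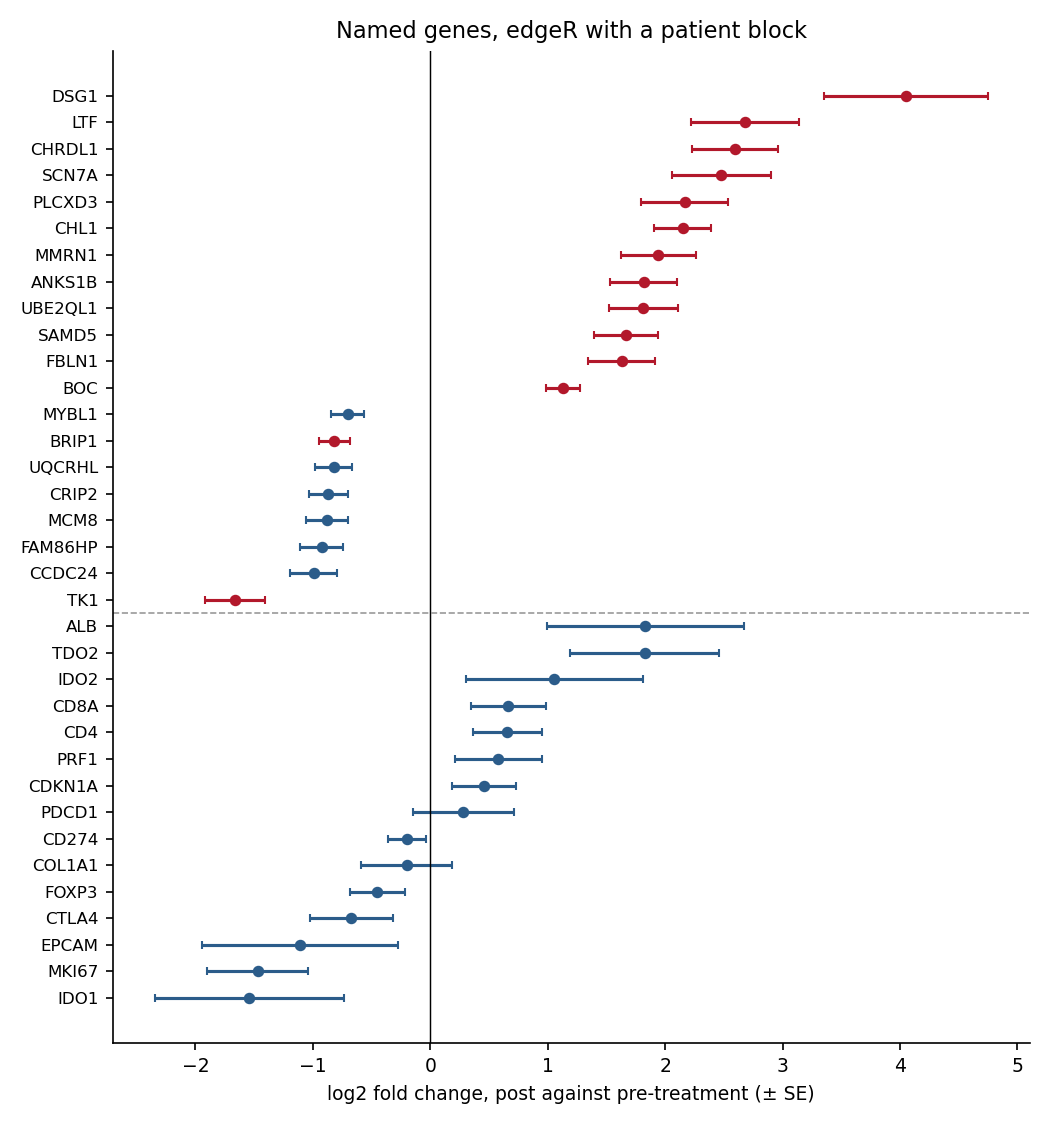
Log2 fold change of post- against pre-treatment libraries (x axis, bars ± SE from the edgeR fit with a patient term, 13 pairs) for the genes of the naming rule, above the dashed line those chosen by their result and below it the study genes. Red marks an adjusted p under 0.05, and the 2 red genes left of 0 are TK1 and BRIP1.

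In all, 16278 genes were tested and 16 passed an adjusted p of 0.05, 14 higher and 2 lower after treatment. The median log2 fold change of all genes was -0.02, and 3943 genes had an unadjusted p under 0.05, against 813.9 given by chance. Only 2 falling genes passed, so the next by p were named as not passing. They were CCDC24 (-0.99 ± 0.20, SE), FAM86HP (-0.92 ± 0.19), MCM8 (-0.88 ± 0.18), CRIP2 (-0.87 ± 0.17), UQCRHL (-0.82 ± 0.16) and MYBL1 (-0.70 ± 0.14), with adjusted p-values of 0.0695 to 0.0705. Without the 1 pair whose change ran most against the others these 6 passed, CCDC24 with an adjusted p of 0.00181 and MYBL1 with 0.00758. That pair was singled out by its own change, which favours such passes. FAM86HP, a pseudogene, and UQCRHL have near-identical relatives, so their counts are uncertain. The count of 16 depended on the model and the patients. It was 2417 with DESeq2, 3878 with limma-voom and quality weights, 1 without the patient block, 1 without the 2 patients of the smaller library set and 1 with the hepatocyte score as a covariate. It was 4005 without the 1 pair whose change ran most against the others, and 2 to 15 without any other patient.

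Lists of adipocyte, acute phase, macrophage, Schwann cell and mast cell genes rose, each with an adjusted p of 0.518 by camera with an estimated correlation. The list of adipocyte genes rose by a mean of 1.48 ± 1.27 log2 CPM (SD, n = 13), in 12 of 13 patients. The list had only 5 of 10 members past the count filter, without ADIPOQ, LEP, CIDEC, CIDEA and FABP4, and cannot show a rise of fat cells. All 5 of its tested members rose when adjusted over the list alone and 0 over all genes, among them LPL, lipoprotein lipase (1.32 ± 0.32, SE), AQP7, a glycerol channel (1.86 ± 0.45), GPD1 (2.06 ± 0.56) and PLIN4, a lipid droplet protein (1.16 ± 0.37). The acute phase list, of plasma proteins made by the liver in inflammation, rose by 1.25 ± 1.32 (SD, n = 13) in 11 of 13 patients. Of its 12 members 11 rose when adjusted over the list alone and 0 over all genes, with SERPINA3 at 0.84 ± 0.24 (SE), LBP at 1.37 ± 0.41, ITIH4 at 1.79 ± 0.54 and HP, haptoglobin, at 1.41 ± 0.47. HP is also in the hepatocyte list, all 22 members of which had a positive log2 fold change, so more liver tissue cannot be told apart here. The macrophage list rose by 0.62 ± 0.58 (SD, n = 13) in 12 of 13 patients, with 4 of 17 members past the threshold over the list alone and 0 over all genes. These were the scavenger receptors CD163 (0.86 ± 0.19, SE) and MARCO (1.53 ± 0.37), the complement receptor VSIG4 (0.91 ± 0.19) and APOE (1.48 ± 0.47). The Schwann cell list rose by 0.61 ± 0.56 (SD, n = 13) in 12 of 13 patients, with 3 of 6 members past the threshold over the list alone, among them CDH19 (1.5 ± 0.36, SE) and NGFR (1.01 ± 0.37), and 0 over all genes. The mast cell list rose by 0.96 ± 1.05 (SD, n = 13) in 11 of 13 patients. Of its 8 members 7 rose over the list alone and 0 over all genes, among them MS4A2, a chain of the IgE receptor (1.53 ± 0.46, SE), HDC, which makes histamine (1.21 ± 0.42), HPGDS (0.62 ± 0.20) and KIT (0.71 ± 0.26).

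These 5 of 48 lists passed, each with an adjusted p of 0.0398 by the exact sign-flip permutation test (n = 13). No list passed with the median over list members, without the patient block or without the 2 patients of the smaller library set. The same held with the hepatocyte score as a covariate. In each of these settings the count of lists past the threshold was 0. It was 13 without the 1 pair that changed against most others, and 0 or 1 without any other patient. Of the patients left out in turn, 10 gave 0 and 2 gave 1.

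**Figure D2:**
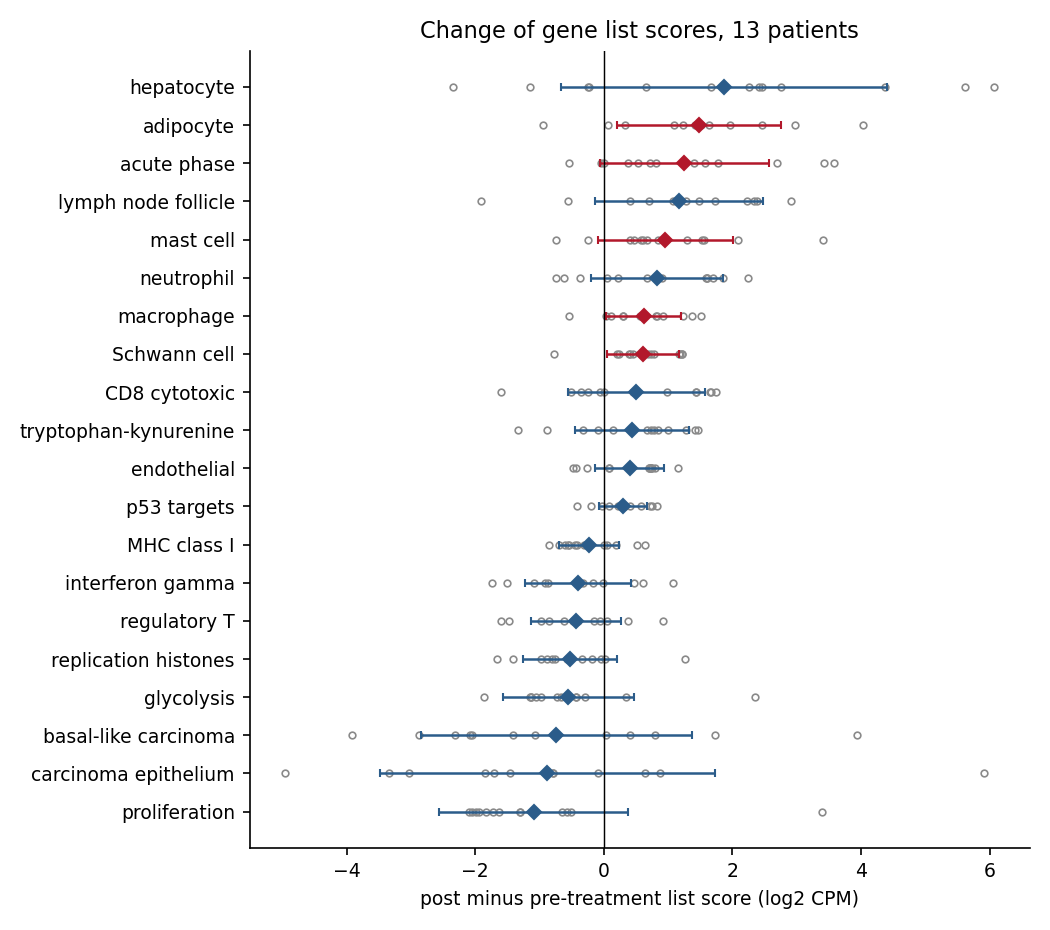
Difference of post- minus pre-treatment list scores in log2 CPM (x axis) for 20 gene lists, with 1 open circle per patient (13 in each row), the mean as a diamond and bars of ± SD. The 5 lists in red passed an adjusted p of 0.05, and the proliferation score was lower in 12 of 13 patients.

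Hepatocyte genes, such as ADH1B (2.40 ± 0.72, SE), ASGR1 (2.00 ± 0.61), SERPINA1 (0.97 ± 0.32) and HP (1.41 ± 0.47), had a mean change of 1.87 ± 2.53 (SD, n = 13), higher in 9 of 13 patients, and missed the threshold (adjusted p = 0.0947, exact sign-flip permutation test). Of the 22 members 21 rose when adjusted over the list alone and 0 over all genes. The 22 proliferation genes, which act in DNA replication and mitosis, had a mean change of -1.09 ± 1.47 (SD, n = 13), lower in 12 of 13 patients (adjusted p = 0.0947, exact sign-flip permutation test). Over the list alone 20 of the 22 fell and over all genes 0 did. Examples are the mitotic kinase AURKB (-1.42 ± 0.33, SE), the motor KIF11 (-1.39 ± 0.34), the transcription factor FOXM1 (-1.28 ± 0.33) and UBE2C (-1.93 ± 0.52). Replication histone genes had a mean change of -0.53 ± 0.73 (SD, n = 13) with the same adjusted p, and 6 of 10 fell over the list alone and 0 over all genes. Their examples are HIST1H1E (-0.48 ± 0.10, SE) and HIST1H2AG (-1.15 ± 0.36). The list of p53 target genes had a mean change of 0.29 ± 0.37 (SD, n = 13, adjusted p = 0.0947), with 6 of 19 members higher and 1 lower over the list alone and 0 over all genes. SESN1 (0.85 ± 0.17, SE) and TP53INP1 (1.04 ± 0.22) were higher in 13 of 13 patients. Carcinoma epithelial genes had a mean change of -0.88 ± 2.61 (SD, n = 13, adjusted p = 0.481), and KRT7 (-1.47 ± 0.60, SE) and KRT19 (-1.72 ± 0.80) did not pass with the 13 pairs. With the hepatocyte score as a covariate the change of the epithelial list turned sign, to 0.42. Without the 1 pair that changed against most others, the proliferation score fell by 1.47 ± 0.60 (SD, 12 patients, lower in each; adjusted p = 0.00781, exact sign-flip permutation test). The hepatocyte score then rose by 2.22 ± 2.29 (adjusted p = 0.0298) and the epithelial score fell by 1.45 ± 1.68 (adjusted p = 0.0306), with KRT19 past the threshold over all genes (-2.03 ± 0.52, SE, adjusted p = 0.0147), and replication histone genes fell by 0.68 ± 0.52 (adjusted p = 0.0117). That pair was singled out by its own change, which by itself makes the remaining 12 more alike.

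**Figure D3:**
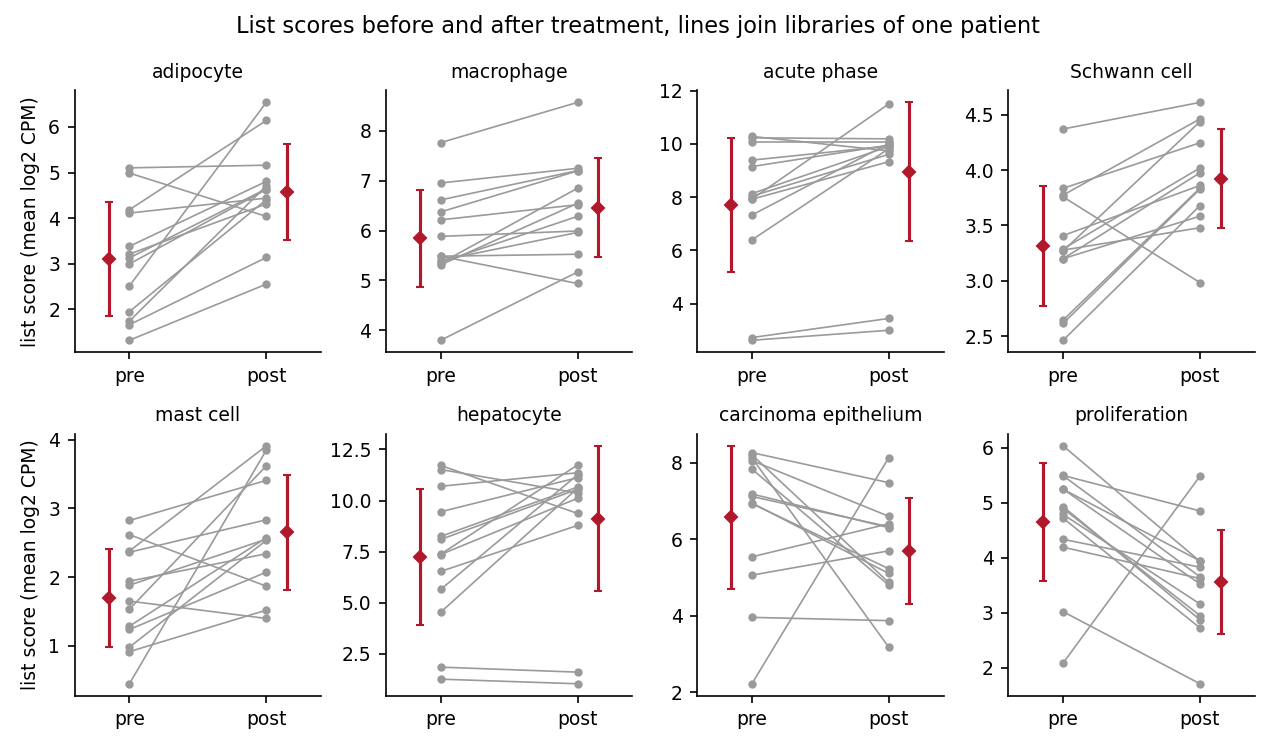
List scores (y axis, mean log2 CPM of the members) before and after treatment for 8 gene lists, with grey lines joining the 2 libraries of 1 patient and red diamonds with bars giving the mean ± SD of the 13 libraries. The proliferation score was lower after treatment in 12 of 13 pairs and the macrophage score higher in 12 of 13.

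The changes of the hepatocyte, epithelial and proliferation scores were related over the patients by Pearson's r, while Spearman's rho missed the threshold after adjustment over the 4 relations computed. Between the hepatocyte and epithelial scores r was -0.68 (n = 13, permutation p = 0.0089, adjusted 0.0119) and rho -0.60 (permutation p = 0.0343, adjusted 0.125). Without the 2 patients farthest from the median hepatocyte change r was -0.62 (permutation p = 0.0415), and without the smaller library set -0.71 (n = 11). Between the hepatocyte and proliferation scores r was -0.63 (permutation p = 0.00875, adjusted 0.0119) and rho -0.49 (permutation p = 0.0939, adjusted 0.125). Between the epithelial and proliferation scores r was 0.83 (permutation p = 0.0041, adjusted 0.0119) and rho 0.53 (permutation p = 0.0674, adjusted 0.125). Both relations of the proliferation score missed the threshold without the 2 patients farthest from the median change of the other score. Then r was -0.47 (permutation p = 0.145) with the hepatocyte score and 0.55 (permutation p = 0.0853) with the epithelial score. The pair that changed most against the others was among the 2 patients each time. Without the smaller library set r was -0.67 and 0.88 in turn (n = 11). The changes of the hepatocyte and macrophage scores showed no relation past the threshold (r = 0.13, permutation p = 0.658, adjusted 0.658, and rho = 0.12, permutation p = 0.709, adjusted 0.709). Without the 2 farthest patients r was 0.099 (permutation p = 0.772), and without the smaller set 0.098. The smaller set holds 2 patients, too few for a value of its own.

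Genes of cornified epidermis were present in some post-treatment libraries. KRT1, a keratin of the upper epidermis, was above 50 CPM in 4 of 13 post-treatment and 0 of 13 pre-treatment libraries. In those 4 libraries it ranged from 87.3 to 694.9 CPM, KRT10 from 113.3 to 1036 CPM and FLG2, a filaggrin-family protein, from 93.5 to 1163 CPM, while the highest KRT1 level in the pre-treatment libraries was 0.57 CPM. DSG1 is also an epidermal gene. Its log2 fold change was 3.63 without the 4 patients concerned (adjusted p = 0.0016) and 3.38 without 3 of them, with the pair that changed against most others kept (adjusted p = 0.137). Without all 4 patients 4381 genes passed, and without those 3 the count was 4.

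Among the study genes of the tryptophan and immune axis, none passed the threshold over all genes with the 13 pairs. Without the 1 pair that changed most against the others TDO2 (2.12 ± 0.59, SE, adjusted p = 0.0205) and CD4 (0.83 ± 0.25, adjusted p = 0.0296) passed. Leaving out a pair for its own change makes the others more alike, so p-values without that pair are too small. IDO1 had a log2 fold change of -1.54 ± 0.80 (SE, lower in 8 of 13 patients, adjusted p = 0.249), IDO2 of 1.06 ± 0.76 (adjusted p = 0.397) and TDO2, the liver enzyme, of 1.83 ± 0.64 (higher in 10 of 13 patients, adjusted p = 0.126). The tryptophan and kynurenine list had a mean change of 0.44 ± 0.88 (SD, n = 13, adjusted p = 0.289, exact sign-flip permutation test). Over the list alone KMO (1.43 ± 0.44, SE), HAAO (1.83 ± 0.59) and TDO2 rose and the amino acid transporter SLC7A5 (-0.99 ± 0.26) fell. With the hepatocyte score as a covariate the log2 change turned sign for IDO2 (-1.19), CD4 (-0.022), PRF1 (-0.13) and PDCD1 (-0.24). It also did so for the tryptophan and kynurenine list (-0.18) and the list of CD8 cytotoxic genes (-0.10). The T-cell genes CD8A (0.66 ± 0.32, SE), CD4 (0.66 ± 0.29) and FOXP3 (-0.45 ± 0.23), the cytotoxic gene PRF1 (0.58 ± 0.37) and the checkpoint genes CD274 (-0.20 ± 0.16), PDCD1 (0.28 ± 0.43) and CTLA4 (-0.67 ± 0.35) did not pass, nor did CDKN1A (0.46 ± 0.27). GZMB and IFNG were below the count filter, so a change in them was not detectable at this depth. MKI67 had a log2 fold change of -1.47 ± 0.43 (SE, lower in 12 of 13 patients, adjusted p = 0.108), EPCAM of -1.11 ± 0.83, COL1A1 of -0.20 ± 0.39 and ALB, albumin, of 1.83 ± 0.84, none past the threshold. Without that pair MKI67 passed (-1.72 ± 0.21, SE, adjusted p = 0.000471). The list of CD8 cytotoxic genes had a mean change of 0.51 ± 1.06, regulatory T-cell genes of -0.44 ± 0.70 and interferon gamma genes of -0.40 ± 0.82 (SD, n = 13 each), with adjusted p-values of 0.289, 0.16 and 0.289 by the exact sign-flip permutation test.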

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

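The fits without patients with epidermal genes, and the list fits with tissue scores as covariates, were chosen after the data were seen. The main count of 16 genes became 2417 with DESeq2 and 3878 with limma-voom and quality weights, and both sets held all 16. It was 41 without a count filter (37 higher, 4 lower), 48 with the epithelial score, 8 with library size and 1 with the hepatocyte score as a covariate. It was 1 without the replicate block, 1 without the 2 patients of the smaller library set, 4381 without the 4 patients with epidermal genes and 4 without 3 of them. Leaving out each patient in turn gave 2 to 4005 genes. The 5 lists became 0 with the median over members, 0 without the smaller set, 0 with no replicate block, 0 with the hepatocyte score as a covariate, 0 with camera and an estimated correlation, 19 with camera and a preset correlation and 15 without the patients with epidermal genes. Leaving out each patient in turn gave 0 to 13 lists. For these moves the cause was not tested, except that fewer patients enter the fits that leave patients out. The 4 patients with epidermal genes include the pair that changed most against the others, and leaving out that pair alone gave the 4005 genes and 13 lists. The rise to 4381 genes and 15 lists can therefore not be assigned to epidermis. The gene count stayed within 1.5 times with DESeq2 or upper-quartile size factors and a stricter filter. The list count did so with DESeq2 size factors, no count filter, other prior counts, the epithelial score and fry.

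With the hepatocyte score as a covariate the log2 change turned sign for ALB (-0.17), IDO2 (-1.19), CD4 (-0.022), PRF1 (-0.13), PDCD1 (-0.24), COL1A1 (0.062) and EPCAM (0.30), and for the lists of tryptophan genes (-0.18), CD8 cytotoxic genes (-0.10), epithelial genes (0.42) and basal-like carcinoma genes (0.42). EPCAM was 0.43 with the epithelial score. COL1A1 was 0.17 with no replicate block, 0.042 without the 3 patients, and -0.33 to 0.033 with each patient left out. None of these genes or lists passed the threshold in the main fit, and the cause was not tested. Depth limits genes near the count filter, such as GZMB and IFNG.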

Other observations

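Further lists did not pass the threshold with the 13 pairs. Without the 1 pair that changed most against the others the lists of lymph node follicles (1.42 ± 0.98, SD, 12 pairs, adjusted p = 0.0117, exact sign-flip permutation test), glycolysis (-0.79 ± 0.55, adjusted p = 0.0117), endothelium (0.48 ± 0.48, adjusted p = 0.0298) and heat shock (-0.44 ± 0.45, adjusted p = 0.0306) passed. That pair was left out for its own change, which by itself makes the other pairs more alike. Of 6 genes of lymph node follicles and lymphatic vessels, 4 rose over the list alone and 0 over all genes, VCAM1 (1.18 ± 0.29, SE), PROX1 (1.62 ± 0.43), LYVE1 (1.42 ± 0.42) and CLU (1.70 ± 0.58), and the list had a mean change of 1.17 ± 1.31 (SD, n = 13, adjusted p = 0.0898, exact sign-flip permutation test). The follicle chemokines CCL19 (1.06 ± 0.60, SE) and CCL21 did not pass. PROX1 and CLU are also liver genes, and with the hepatocyte score as covariate the lymph_node_follicle mean change was 0.34 (adjusted p = 0.789). The neutrophil list had a mean change of 0.82 ± 1.02 (SD, n = 13), with MMP8 (3.25 ± 0.71, SE) and S100A8 (1.92 ± 0.48) past the threshold over the list alone. The endothelial list had a mean change of 0.40 ± 0.54 (SD, n = 13), with VWF (1.31 ± 0.27, SE), CDH5 (0.62 ± 0.20) and ENG (0.54 ± 0.18) past it over the list alone. Both had an adjusted p of 0.0947. Heat shock genes had a mean change of -0.31 ± 0.65 (SD, n = 13, adjusted p = 0.289). Glycolysis genes had a mean change of -0.55 ± 1.02 (SD, n = 13, adjusted p = 0.267), and TPI1 (-0.57 ± 0.15, SE) alone of 16 fell over the list alone. MHC class I genes had a mean change of -0.23 ± 0.47 (SD, n = 13, adjusted p = 0.289) and basal-like carcinoma genes of -0.74 ± 2.11 (SD, n = 13, adjusted p = 0.458).

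The tests on the pair that changed most against the others, every fit that leaves out that pair for the proliferation score or patients with epidermal genes, and the list fits with tissue scores were chosen after the data had been seen. Exchanging pre and post labels within drawn sets of patients, 1 of 100 splits, the real one, gave as many as 16 genes, and the highest of the others gave 2. For the lists, 1 of 100 splits gave as many as 5, and the highest of the others gave 3. Chance alone is thereby unlikely for both counts, at 1 in 100, the smallest share that 100 splits can give. The labels do not give the organ of each biopsy, and in some patients the hepatocyte score was low at both time points. More liver tissue in the post-treatment biopsies could contribute to the 16 genes. With the hepatocyte score as a covariate they kept a median of 0.746 of their log2 fold change (lowest 0.575, all 16 in the same direction, standard errors 1.05 times as large), just under the bound of 0.75 set against that explanation, so it cannot be told apart from treatment. The median share kept was 0.895 with the epithelial score as a covariate. It was 1.11 without the 4 patients who had epidermal genes (15 genes still tested) and 1.01 without 3 of them (14 genes). The 16 genes were called for a change shared by patients, and all 16 moved the same way in at least 10. A high share kept was therefore likely beforehand and does not argue against less carcinoma epithelium or epidermis. For the genes still tested, the log2 fold changes did not rest on the patients with epidermal genes. Without those 3 patients 4 genes passed, 2 of them among the 16.

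The lower proliferation score could follow in part from more liver tissue in the biopsies, which cannot be told apart from treatment because 1 pair decides the test. At no change of the hepatocyte score the change that remained was -0.41 ± 0.42 (SE, 13 pairs, sign-flip permutation p = 0.512) out of -1.09. This share of 0.378 met the rule set beforehand for more liver tissue as the cause. Without the pair that changed most against the others, -1.19 ± 0.23 (SE, 12 pairs, sign-flip permutation p = 0.00391) out of -1.47 remained. That pair was left out for its own change, so the fit without it cannot set that outcome aside. At no change of the epithelial score the remaining change was -0.68 ± 0.25 (SE, sign-flip permutation p = 0.0103) with all pairs. This argues against less carcinoma epithelium as the whole cause. Without that pair it was -1.23 ± 0.22 (SE, sign-flip permutation p = 0.000977), which adds no support because the pair was left out for its own change. An effect of the drugs on dividing cells stays open.

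Over all genes, 2 of 13 pairs had a change that correlated negatively with the mean change of the others, and 1 of them ran most against it. A candidate explanation is that liver tissue and carcinoma epithelium shares differ the other way in that pair. Its hepatocyte score fell and its epithelial score rose after treatment, against the mean changes of both lists. Over 2492 genes that vary little with both scores, 1 pair still had a negative correlation. Those genes were chosen over the libraries of the other pairs, and that pair's epithelial score before treatment lay below all of theirs. The test therefore cannot argue against the shares of these 2 tissues as the cause. Relations to them below a correlation of 0.2, and other tissues such as epidermis, were not removed and stay possible. Pre and post labels exchanged in that pair are left open by the count of 1 pair negative in both gene sets, while the genes of liver-resident macrophages were higher after treatment in 13 of 13 pairs and all 4 libraries with KRT1 above 50 CPM were post-treatment as labelled. A lesion that changed the other way stays open too, so the labels were kept as they are.

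The macrophage score had a remaining change of 0.56 ± 0.21 (SE, sign-flip permutation p = 0.0527) at no change of the hepatocyte score, and without genes of liver-resident macrophages the list rose by 0.53 ± 0.60 (SD, n = 13, higher in 11 patients, sign-flip permutation p = 0.00879). The genes CD5L, MARCO, VSIG4, TIMD4 and FOLR2 of liver-resident macrophages rose by a mean of 1.41 ± 1.07 (SD, higher in 13 of 13 patients). Of these only MARCO and VSIG4 are in the macrophage list. Its other 15 members, CD163 and APOE among them, were not chosen to be absent from liver tissue. Their rise therefore cannot separate liver-resident from other macrophages.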
